A study of Homo sapiens with 4 samples.

How the data were processed

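RiboMethSeq was run on total RNA from 4 samples of HAP1, a near-haploid human cell line of leukaemic origin, with 1 library each. PAF49 and PAF49-GFP, whose labels name no deletion, are called full-length here. The deletions are labelled PAF49delta1/2IDR-GFP and PAF49deltaIDR-GFP. The assay reads 2′-O-methylation from partial alkaline hydrolysis of RNA: a methyl group on the 2′ oxygen of the ribose protects the bond on the 3′ side of that nucleotide, so read ends become rare at the matching position. Per the labels' protocols, RNA was extracted with TRI Reagent and hydrolysed in a bicarbonate buffer, and the end-repaired fragments were made into Illumina libraries with a small RNA kit. The submitters' processing notes name Trimmomatic 0.36 and Bowtie2 2.3.3.1, a read trimmer and an aligner, without giving their role or order. The rRNA reference sequence, the formula of the score, the window of neighbouring positions it uses and any filter on sites are not given in the sources used here.

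The deposited table holds, for each of 108 named rRNA positions, a MethScore per library, which the file header calls raw data. The scores were treated as a fraction because every value the authors deposited lies from 0 to below 1, and higher values are read as stronger protection, as is usual for such scores. Whether a score equals the methylated share of molecules, and whether low scores were set to 0, is not given in the sources used here. A further block, headed as fold change by the authors, holds the ratio of each library's score to that of PAF49-GFP at the same position. This was checked by recomputing the ratio, rounded to 2 decimals: 428 of 428 deposited fold values lay within 0.01 of it, leaving out 28S-Um2044, where PAF49-GFP is listed at 0 and the deposited folds of both deletion libraries equal the ratio to PAF49. No fold to PAF49-GFP is given here for that site. The fold block was used only for this check and for the few values credited to it below.

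The table gives no read counts or coverage, so the depth behind each score is unknown, and no confidence interval, floor or counting error could be attached to any value. Scores near 1 have little room to vary, whatever the depth. Reads from all copies of the ribosomal DNA are pooled in one score per position, so a score is an average over copies and over ribosomes and precursors in the cell. Site names and positions are printed as deposited. Gene names were looked up in a RefSeq gene table of GRCh38.p14, in which PAF49 is a synonym of POLR1G and 5 copies each of the 18S, 5.8S and 28S rRNA genes are listed. No coordinates are given, because the deposited table names no genome build.

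With 1 library per group there is no spread between replicates, and no significance test between groups and no p-value was computed. List medians, and the patterns weighed in the closing observations, were set against random lists, random pairings or equal shares over sites of these same libraries. Before the data were examined, the following choices were fixed. For each of 4 comparisons (PAF49-GFP minus PAF49, each deletion minus PAF49-GFP, and PAF49deltaIDR-GFP minus PAF49delta1/2IDR-GFP), the score difference was taken at every site, and sites differing by 0.1 or more were counted in each direction. The comparison of PAF49-GFP with PAF49, the only pair of libraries with no deletion, served as the yardstick for how far libraries differ. It cannot separate variation between libraries from an influence of the tag. The text names, for each comparison, all sites that differed by 0.1 or more, at most the 10 largest per direction, and where fewer than 5 reached 0.1 in a direction the 5 largest of that direction, in addition to any site at which both deletion libraries lay beyond both full-length libraries by 0.1 or more. A site outside this rule is said to be chosen after its values were seen. For the 4 libraries together, sites were counted at which both deletion libraries lay above or below both full-length libraries, with no minimum gap and with a gap of 0.1 or more, beside the same count for the other ways to pair the libraries.

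Also fixed were 18 site lists: the 3 rRNAs; the 4 modified bases; sites with a mean score over the 4 libraries of 0.9 or above, from 0.5 to 0.9, and under 0.5; 3 stretches of the 18S numbering (up to 600, above 600 up to 1200, above 1200) and 3 of the 28S numbering (up to 1700, above 1700 up to 3400, above 3400); and sites with and without another methylated site within 10 nt. Each list's median difference was placed among 10000 random lists of the same size matched on mean score in 5 bins (seed 1). This percentile describes these libraries only, and it is void for the lists made by mean score, which the matching fixes. For the comparisons that share PAF49-GFP as control, 1000 pairs of unchanged libraries were simulated. The spread at each site was set from the size of the 1 difference between the full-length libraries there. A single difference does not measure a site's spread, so sites at which these libraries happened to be close received little noise.

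The alternatives were other thresholds (0.05 and 0.2), libraries shifted to the same median, quantile normalisation, limits on mean score (at least 0.2, and below 0.9), scores clipped to the range from 0 to 1, a difference of 1 on the log2 odds scale with 0.05 added to the score and to its complement, and PAF49 or the mean of both full-length libraries as control. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The counting of differing sites was tested on simulated data with 108 sites and a noise SD of 0.0249 per library: over 20 runs, 99.8% of sites shifted by 0.2 were called in the right direction and 0.114% of unshifted sites were called. This simulation gave all sites the same spread, whereas between the full-length libraries the SD of the difference was 0.0129 at sites with a mean score of 0.9 or above and 0.0497 from 0.5 to 0.9, and 2 of 108 sites passed 0.1, so the simulated share of unshifted calls is too low for the sites below 0.9. A list of base U sites shifted by 0.05 lay above the central 95% of random lists in 20 of 20 runs, and an unshifted list lay outside it in 1 of 20. The simulated shifts of 0.2 and 0.05 are larger than nearly all site differences and all list medians reported below, so recovery at the sizes seen was not tested.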

Results

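2′-O-methylation of ribosomal RNA was scored in HAP1 cells at 108 positions, of which 39 lie in 18S, 2 in 5.8S and 67 in 28S rRNA. Methylated nucleotides comprised 34 adenosines, 23 cytidines, 30 guanosines and 21 uridines. In human cells most rRNA methyl groups of this kind are placed by fibrillarin, guided by box C/D small nucleolar RNAs, in nucleoli, the sites of rRNA synthesis. PAF49 is the product of POLR1G and a subunit of RNA polymerase I, which transcribes the rRNA precursor. The labels name 2 samples with no deletion, PAF49 and PAF49-GFP, which are taken here as full-length. They also name 2 deletions with the tag, PAF49delta1/2IDR-GFP and PAF49deltaIDR-GFP. GFP is a fluorescent tag, and the series title gives IDR as an intrinsically disordered region, a protein segment with no stable fold. The labels do not say which residues each deletion removes, nor whether the cells also made their own PAF49. Each group had 1 library and an unknown depth, so every difference below stands without a replicate check.

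Most rRNA sites scored high in all 4 libraries. The median MethScore over sites was 0.908 in PAF49, 0.909 in PAF49-GFP, 0.915 in PAF49delta1/2IDR-GFP and 0.913 in PAF49deltaIDR-GFP. In the same order, 60, 56, 62 and 64 sites scored 0.9 or above, and 7, 6, 5 and 6 sites scored under 0.5. Per rRNA, the library medians ran from 0.912 to 0.923 in 18S, from 0.891 to 0.909 in 28S and from 0.833 to 0.849 over the 2 sites of 5.8S rRNA. The 5 sites with a mean score under 0.5 were 18S-Um354, 18S-Gm867, 18S-Cm1272, 28S-Um2044 and 28S-Am3867, and 28S-Um2044 was listed at 0 in PAF49-GFP. Of these, 18S-Cm1272 was chosen after its values were seen. Scores of any pair of libraries correlated across sites with Pearson's r from 0.959 (PAF49 with PAF49deltaIDR-GFP) to 0.991 (PAF49 with PAF49delta1/2IDR-GFP), where sites are not independent replicates.

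How far a site varied depended on its level. The range of a site's score over the 4 libraries had a median of 0.0132 among the 59 sites with a mean score of 0.9 or above, 0.0606 among the 44 sites from 0.5 to 0.9, and 0.117 among the 5 sites under 0.5. At 44 of the 108 sites the range was under 0.02, and the smallest was 0.00376 at 18S-Am668, a site chosen after its values were seen. At 12 sites the range was 0.1 or more, and at none of these was the mean score 0.9 or above.

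**Figure D1:**
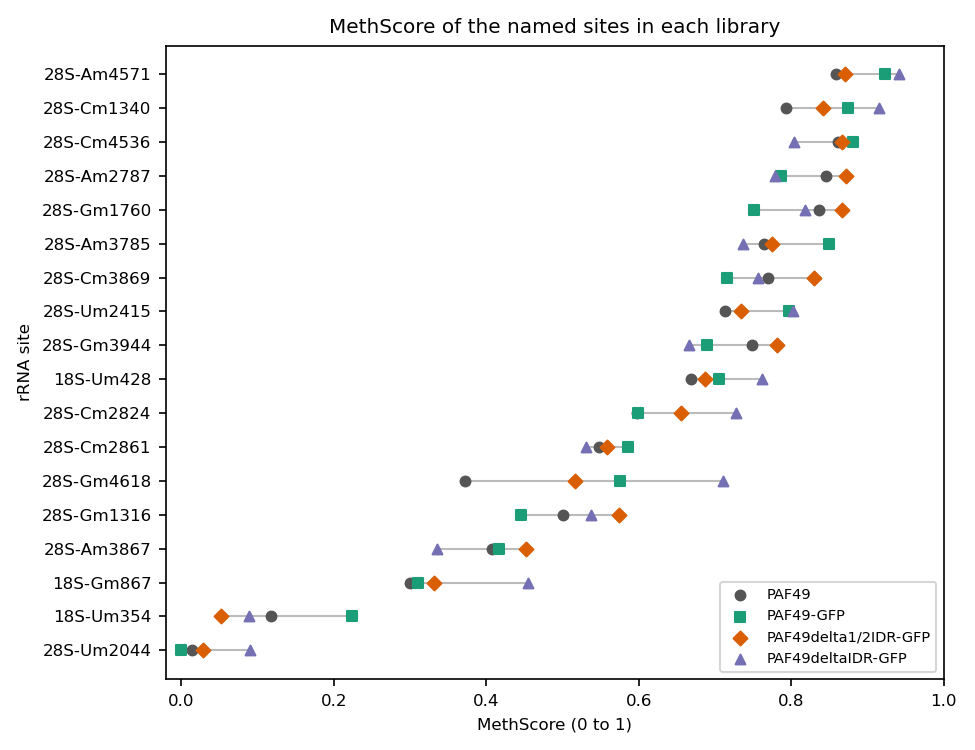
MethScore (0 to 1) of the 18 sites named in the comparisons, in each of the 4 libraries, ordered by mean score; each symbol is 1 library and the grey line spans the range over the libraries. 28S-Gm4618 spans the widest range, from 0.372 in PAF49 to 0.710 in PAF49deltaIDR-GFP.

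The first comparison asked how PAF49-GFP, taken as the tagged full-length protein, differed from PAF49, whose label names no tag. In PAF49-GFP, 28S-Gm4618 scored 0.575 against 0.372 in PAF49, a difference of 0.203. At 18S-Um354, a low-scoring uridine, the score was 0.224 against 0.117, a difference of 0.106. No other site differed by 0.1, and no site was lower by that much. The next largest positive differences were at 28S-Am3785 (0.0854), 28S-Um2415 (0.0840) and 28S-Cm1340 (0.0805), and the most negative were at 28S-Gm1760 (-0.0861), 28S-Gm3944 (-0.0592), 28S-Am2787 (-0.0591), 28S-Gm1316 (-0.0554) and 28S-Cm3869 (-0.0536). Over all sites the median difference was 0.00291 with an SD over sites of 0.0352, and 68.5% of sites differed by under 0.02. Scores were higher in PAF49-GFP at 65 sites and lower at 43 as deposited, 63 and 45 with libraries shifted to the same median, and 52 and 44 after quantile normalisation, which left the rest tied. Quantile normalisation also left the difference at 18S-Um354 at 0, so that 28S-Gm4618 alone stayed past 0.1. This 0 is fixed by rank, since 18S-Um354 was the lowest site but 28S-Um2044 in both libraries, and it does not speak to the size of the difference.

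The second comparison set PAF49delta1/2IDR-GFP against the tagged full-length protein. Scores were higher by 0.1 or more at 3 sites of 28S rRNA. These were 28S-Gm1316 (0.574 against 0.445, a difference of 0.130), 28S-Gm1760 (0.866 against 0.751, a difference of 0.116) and 28S-Cm3869 (0.830 against 0.716, a difference of 0.114). 18S-Um354 was the only site lower by 0.1 or more, at 0.0516 against 0.224, a difference of -0.172. Below that size, the largest positive differences were at 28S-Gm3944 (0.0930) and 28S-Am2787 (0.0849). The most negative were at 28S-Am3785 (-0.0748), 28S-Um2415 (-0.0626), 28S-Gm4618 (-0.0589) and 28S-Am4571 (-0.0519). In the authors' deposited table the fold to PAF49-GFP was 1.29 at 28S-Gm1316 and 0.23 at 18S-Um354.

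The SD over sites was 0.0367, close to the 0.0352 between the full-length libraries, and the median difference was 0.00400. Scores were higher at 68 sites and lower at 40 as deposited, but higher at 44 and lower at 64 once libraries were shifted to the same median, and higher at 46 and lower at 51 after quantile normalisation. Against PAF49 the median difference was 0.0104, with higher scores at 83 sites and lower at 25 as deposited, 62 and 46 with libraries shifted to the same median, and 45 and 46 after quantile normalisation. With that control, all 4 of the sites past 0.1 differed by under 0.1: 28S-Gm1316 by 0.0741, 28S-Cm3869 by 0.0609, 28S-Gm1760 by 0.0298 and 18S-Um354 by -0.0658. There, 28S-Gm4618 was the only site past 0.1, with a difference of 0.144. At each of the 4 sites past 0.1 against PAF49-GFP, PAF49-GFP scored highest or lowest of all libraries. A site past 0.1 against PAF49-GFP but not against PAF49 must have PAF49-GFP beyond PAF49 and the deletion compared. Only PAF49deltaIDR-GFP was therefore free to differ, and this does not show which full-length library stood apart. The 5 highest sites against PAF49-GFP were the 5 lowest of PAF49-GFP minus PAF49, which holds the same PAF49-GFP score with the opposite sign. Of the 5 most negative sites, all but 28S-Am4571 were among the 5 most positive there. Quantile normalisation left 18S-Um354 at 0, 28S-Cm3869 at 0.0619 and 28S-Gm1760 at 0.0908, kept 28S-Gm1316 past 0.1 and brought 28S-Am3785 to -0.110. The 0 at 18S-Um354 again follows from its rank, the lowest but 28S-Um2044 in both libraries. On the log2 odds scale 18S-Um354 differed by -1.70, and the 3 higher sites stayed short of the threshold of 1, at 0.68 to 0.90.

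The comparison of PAF49deltaIDR-GFP with PAF49-GFP gave 5 sites past 0.1. 18S-Gm867 scored 0.454 against 0.310, a difference of 0.144, and its scores in the other full-length and deletion libraries were 0.299 and 0.332. 28S-Gm4618 scored 0.710 against 0.575, a difference of 0.135, and 28S-Cm2824 scored 0.728 against 0.599, a difference of 0.129. Lower scores were found at 18S-Um354 (0.0883 against 0.224, a difference of -0.135) and 28S-Am3785 (0.737 against 0.849, a difference of -0.112). Sites short of 0.1 included 28S-Gm1316 (0.0922) and 28S-Um2044 (0.0902, with PAF49-GFP listed at 0) among the higher, and 28S-Am3867 (-0.0814), 28S-Cm4536 (-0.0775) and 28S-Cm2861 (-0.0558) among the lower. The authors' deposited table gives a fold of 1.46 at 18S-Gm867, 1.23 at 28S-Gm4618 and 1.21 at 28S-Cm2824.

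The 3 higher sites stayed past 0.1 whichever full-length library served as control. They scored above both of them by 0.144 at 18S-Gm867, 0.135 at 28S-Gm4618 and 0.129 at 28S-Cm2824, although quantile normalisation left 28S-Cm2824 at 0.0807. 28S-Gm4618 was also the site at which the full-length libraries themselves differed most. The lower sites did not hold in this way: against PAF49, 18S-Um354 differed by -0.0292 and 28S-Am3785 by -0.0268, and quantile normalisation left 18S-Um354 at -0.0881. That last value reflects only a swap of rank with 28S-Um2044, as these sites scored 0.0883 and 0.0902 in PAF49deltaIDR-GFP. On the log2 odds scale 18S-Um354 (-1.20) and 28S-Um2044 (1.62, with PAF49-GFP listed at 0) passed the threshold of 1, and the 3 higher sites did not, at 0.75 to 0.80. Set against PAF49, 5 sites were higher by 0.1 or more and 0 lower, with 28S-Cm1340 (0.121) and 28S-Um4620 (0.124, chosen after its values were seen) beside the 3 named. Over all sites the median difference was 0.00310 and the SD 0.0400. Scores were higher at 63 sites and lower at 45 as deposited, higher at 52 and lower at 56 with libraries shifted to the same median, and higher at 48 and lower at 53 after quantile normalisation. Against PAF49 these counts were 62 and 46, 51 and 57, and 43 and 51.

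**Figure D2:**
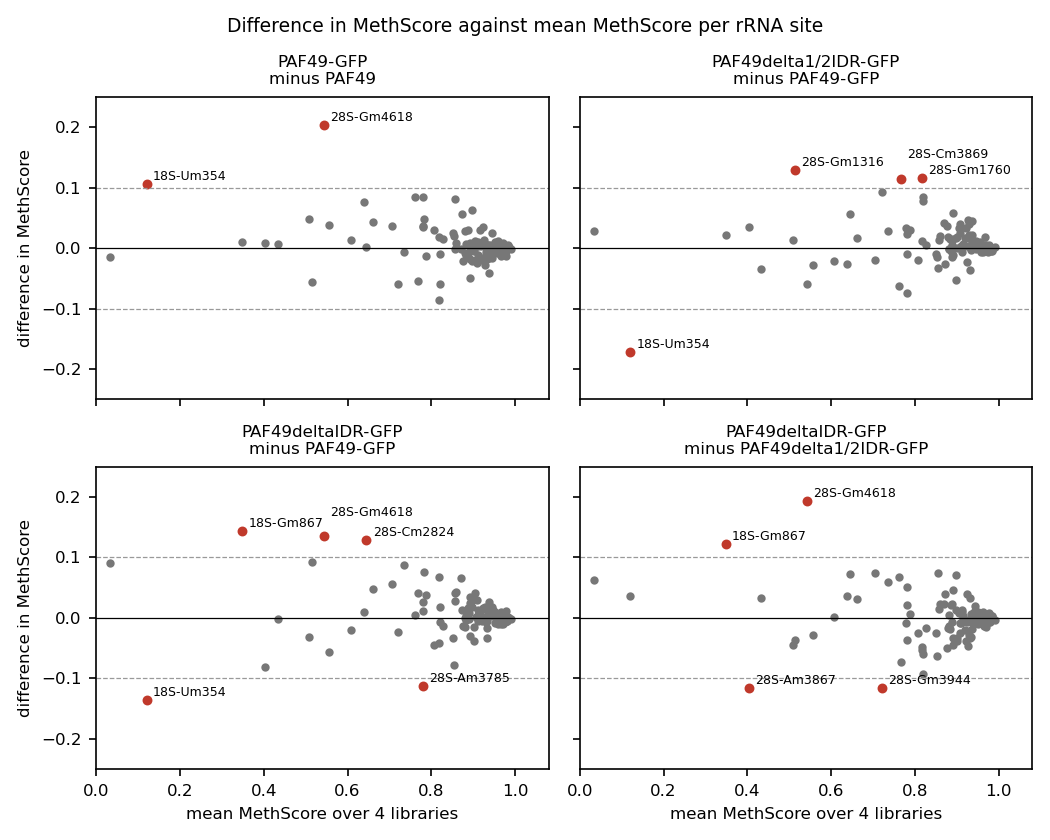
Difference in MethScore (vertical axis) against the mean MethScore over the 4 libraries (horizontal axis) for the 108 sites, 1 panel per comparison; dashed lines mark differences of 0.1 in either direction, and red labelled points are sites at or beyond them. Differences past 0.1 occur only at sites with a mean score below 0.9, and 2, 4, 5 and 4 sites pass in the 4 panels.

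Between the deletions, 28S-Gm4618 and 18S-Gm867 scored higher in PAF49deltaIDR-GFP than in PAF49delta1/2IDR-GFP, by 0.194 and 0.122. 28S-Am3867 scored 0.335 against 0.452, a difference of -0.117, and 28S-Gm3944 scored 0.666 against 0.782, a difference of -0.116. No other site differed by 0.1. The next largest positive differences were at 18S-Um428 (0.0747), 28S-Cm1340 (0.0736) and 28S-Cm2824 (0.0725), and the next most negative at 28S-Am2787 (-0.0920), 28S-Cm3869 (-0.0738) and 28S-Cm4536 (-0.0636). The median difference was -0.00287 and the SD over sites 0.0414. Scores were higher in PAF49deltaIDR-GFP at 49 sites and lower at 59 as deposited, 54 and 54 with libraries shifted to the same median, and 49 and 52 after quantile normalisation.

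All libraries were then compared at once, to find sites at which both deletions lay on the same side of both full-length proteins. No site did so by 0.1 or more between the nearest values, and neither did any site under the other ways of pairing the libraries. The widest gap was at 28S-Cm2824, where both deletions (0.655 and 0.728) lay above both full-length libraries (0.597 and 0.599) by at least 0.0561. Gaps of 0.02 or more in the same direction were seen at 8 sites, among them 28S-Cm3808 (0.0408), 28S-Gm1316 (0.0367), 28S-Am1524 (0.0326) and 18S-Gm867 (0.0213), of which 28S-Cm3808 and 28S-Am1524 were chosen after their values were seen. 18S-Um354 was the only site with a gap of that size in the other direction (-0.0292). These 9 sites compare with 12 at which PAF49 and PAF49delta1/2IDR-GFP lay together beyond the other libraries by 0.02 or more (5 above, 7 below). Pairing PAF49 with PAF49deltaIDR-GFP gave 1 site at that gap.

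With no minimum gap, both deletions lay above both full-length libraries at 27 sites and below at 6. This split depended on scaling, and was 19 and 23 with libraries shifted to the same median and 9 and 14 after quantile normalisation. These 33 sites compare with 36 if all 3 ways of pairing 4 libraries were equally common. Pairing PAF49 with PAF49delta1/2IDR-GFP gave 50 sites, and pairing PAF49 with PAF49deltaIDR-GFP gave 25. PAF49delta1/2IDR-GFP lay outside the range of the full-length libraries by 0.05 or more at 5 sites, 4 above and 1 below, and PAF49deltaIDR-GFP at 8 above and 2 below.

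**Figure D3:**
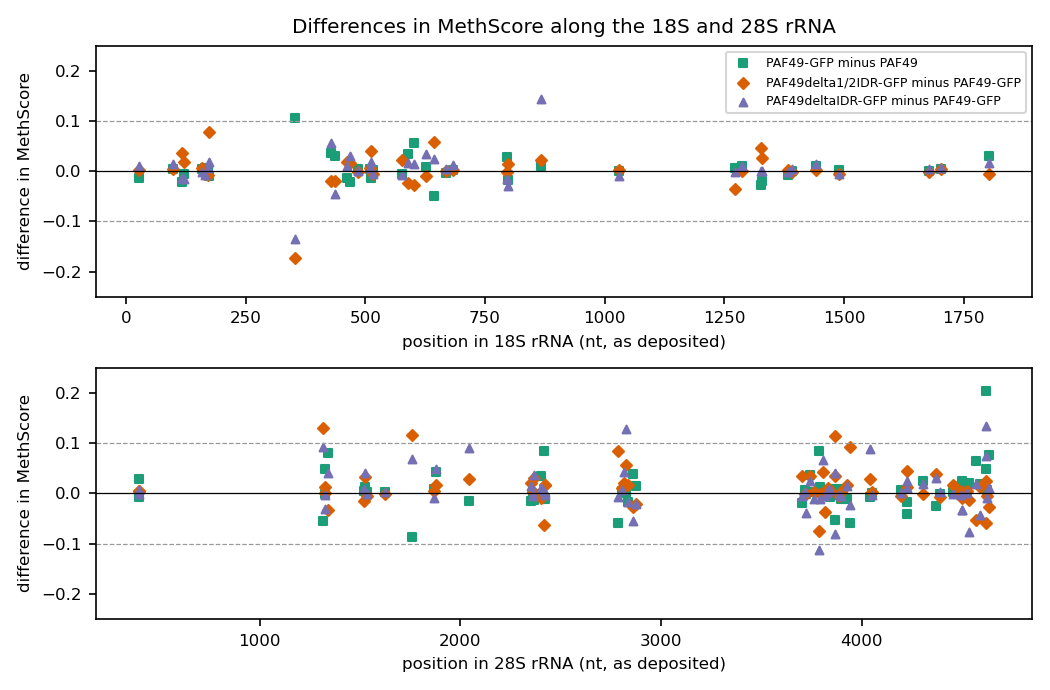
Difference in MethScore (vertical axis) of PAF49-GFP minus PAF49 (green squares) and of each deletion minus PAF49-GFP (orange diamonds and violet triangles) along the deposited positions of 18S (upper panel) and 28S rRNA (lower panel); dashed lines mark differences of 0.1. The most negative point, -0.172, and the next, -0.135, both lie at 18S-Um354, and the highest, 0.203, lies at 28S-Gm4618 near the end of the covered stretch.

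Site lists by rRNA, base and region showed small median differences. In 18S rRNA the medians of the 4 comparisons, in the order given above, were 0.00291, 0.00212, 0.00385 and 0.00235, and in 28S rRNA 0.00291, 0.00546, 0.00171 and -0.00418. The 2 sites of 5.8S rRNA gave 0.00680, 0.00903, 0.00720 and -0.00183. By base, adenosine sites had medians of 0.00358, 0.00325, -0.000159 and -0.00373, cytidine sites 0.00181, 0.0106, 0.00589 and -0.00467, guanosine sites 0.00224, 0.00297, 0.00428 and -0.00418, and uridine sites 0.00858, 0.00307, 0.00546 and 0.0105. Uridine sites thus had a positive median in PAF49deltaIDR-GFP minus PAF49delta1/2IDR-GFP, which was 0.0130 with libraries shifted to the same median and 0.0133 after quantile normalisation. It lay at the 98.9 percentile of matched random lists, with 12 of the 21 sites higher and 9 lower.

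Along 18S rRNA, medians in the same order were 0.00360, 0.00399, 0.00546 and -0.000734 up to position 600, 0.00217, 0.00191, 0.0130 and 0.00351 above 600 up to 1200, and 0.00291, 0.000181, 0.00337 and 0.00444 above 1200. Along 28S rRNA they were 0.00404, 0.00289, 0.00470 and 0.00280 up to 1700, -0.000788, 0.0166, 0.00517 and -0.00467 above 1700 up to 3400, and 0.00403, 0.00363, 0.00120 and -0.00539 above 3400. Sites with another methylated site within 10 nt (55 sites) had medians of 0.00249, 0.00564, 0.000508 and -0.00437, and the other 53 sites 0.00363, 0.00270, 0.00589 and 0.00238. The last of these lay at the 98.0 percentile. By mean score, medians were 0.00217, 0.00307, 0.000796 and -0.00365 at 0.9 or above, 0.0114, 0.0128, 0.0124 and -0.00288 from 0.5 to 0.9, and 0.00883, 0.0213, -0.00229 and 0.0367 under 0.5.

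Among 60 list medians with a percentile, the 2 given above lay outside the central 95% of random lists, where chance gives 3. With libraries shifted to the same median, 0, 13, 5 and 2 of the 18 list medians of the 4 comparisons did not keep their sign, and after quantile normalisation 9, 14, 10 and 6 did not. A median of 0 counts here as a sign not kept. After quantile normalisation 8, 4, 6 and 7 medians were positive, 3, 9, 10 and 6 negative, and the rest were 0 and not reversals.

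Differences of the deletions from PAF49-GFP were correlated across sites (Pearson's r 0.419, Spearman's rho 0.292, 61 of 108 sites with the same sign). Unchanged libraries set against the same control gave a median r of 0.517 in simulation, with the central 95% of values from -0.109 to 0.823. The simulated spread at each site rested on 1 difference, so the simulated values in this paragraph are only a rough guide. The observed covariance was 0.000615, beside 0.000547 in simulation. With PAF49 as the shared control, r was 0.613 and rho 0.415, and 65 of 108 sites had the same sign. With a different full-length control for each deletion, r was 0.532 (PAF49delta1/2IDR-GFP against PAF49) or -0.192 (PAF49delta1/2IDR-GFP against PAF49-GFP), and rho was 0.363 or -0.146. Of the 3 sites past 0.1 in the higher direction in each deletion, 0 were shared, beside 0.0833 for independent lists and 0.488 in simulation. In the lower direction 18S-Um354 was shared by the list of 1 and the list of 2, beside 0.0185 and 0.464, so that part of this overlap may come from the shared control. At this site PAF49-GFP scored highest of all libraries, and neither deletion differed from PAF49 by 0.1.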

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

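Taking the nearest full-length library as control, and leaving out sites at which the full-length libraries differ by 0.1 or more, were alternatives chosen after seeing the data, as were the scalings and the limit on mean score applied to the count with no minimum gap. The 4 comparisons are taken in the order PAF49-GFP minus PAF49, PAF49delta1/2IDR-GFP minus PAF49-GFP, PAF49deltaIDR-GFP minus PAF49-GFP, and PAF49deltaIDR-GFP minus PAF49delta1/2IDR-GFP, with 2, 4, 5 and 4 sites past 0.1. A shift of libraries to the same median gave the same counts. Clipping and leaving out sites with a mean score of 0.9 or above could not move them, since every score lies from 0 to below 1 and no site left out differs by 0.1. A threshold of 0.05 gave 13, 13, 15 and 18 sites, and 0.2 gave 1, 0, 0 and 0. Quantile normalisation gave 1, 2, 3 and 5, and a difference of 1 on the log2 odds scale gave 1, 1, 2 and 1, of which 1, 0, 1 and 1 were higher. Only the first comparison moved by over 1.5 times at sites with a mean score of at least 0.2, to 1 site. With PAF49 as control, PAF49delta1/2IDR-GFP had 1 site, a higher one, and PAF49deltaIDR-GFP 5 higher and 0 lower, in place of 3 higher and 2 lower. The mean of both full-length libraries as control gave 2 and 3, and the nearest full-length library 0 and 3, which by construction can only lower the count. Without sites differing between the full-length libraries, the counts were 3 and 3. A gap of 0.05 in place of 0.1 gave 1 site at which both deletions lay beyond both full-length libraries, against 0. At that gap, pairing PAF49 with PAF49delta1/2IDR-GFP gave 5 sites and pairing PAF49 with PAF49deltaIDR-GFP gave 0. The mean score per library was 0.842 for PAF49, 0.849 for PAF49-GFP, 0.857 for PAF49delta1/2IDR-GFP and 0.856 for PAF49deltaIDR-GFP, and in that order the medians at sites with a mean score of at least 0.2 were 0.909, 0.909, 0.917 and 0.914. Without matching on mean score, 7 of 72 list medians lay outside the central 95% against 3.6 by chance, and with means in place of medians 0 of 60. Of the 15 named differences past 0.1, all kept their size class after the shift to the same median, 6 fell short of 0.1 after quantile normalisation, and 6 of the 9 against PAF49-GFP fell short with PAF49 as control. The 6 after quantile normalisation include every one at 18S-Um354, where rank sets the value. At each of the 6 that fell short with PAF49 as control, PAF49-GFP scored highest or lowest of the 4 libraries. For such a site PAF49-GFP must lie beyond PAF49 and the deletion compared, so only the other deletion was free to differ. The losses therefore cannot be assigned to the scores of either full-length library. Quantile normalisation brought 28S-Am3785 (-0.110, PAF49delta1/2IDR-GFP minus PAF49-GFP) and 28S-Am2787 (-0.103, PAF49deltaIDR-GFP minus PAF49delta1/2IDR-GFP) past 0.1. Of the 11 named differences short of 0.1 against PAF49-GFP, 4 changed sign with PAF49 as control. Why the 6 differences fell short with PAF49 as control was not tested. Except for the nearest-library control, the cause of the other moves was not tested either. No paired analysis was possible because each group has 1 library. Depth is unknown, so its limits on these values are unknown too.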

Other observations

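Tests of regional differences, of the modified base and of the excess over the deletion pairing were chosen after the result was seen; that of an overall shift on the count above equal shares was chosen before. The sites named in this paragraph, where outside the naming rule, were picked for their values. 28S-Um4620 lies 2 nt from 28S-Gm4618, the most variable site, and its scores took the same order except among the middle libraries: 0.720 in PAF49, 0.769 in PAF49-GFP, 0.793 in PAF49delta1/2IDR-GFP and 0.844 in PAF49deltaIDR-GFP. 28S-Am3867 and 28S-Cm3869 are likewise 2 nt apart, and both scored lower in PAF49deltaIDR-GFP than in PAF49delta1/2IDR-GFP, by differences of -0.117 and -0.0738. Both were higher in PAF49delta1/2IDR-GFP than in PAF49-GFP (0.0353 and 0.114). They went opposite ways in PAF49deltaIDR-GFP minus PAF49-GFP (-0.0814 and 0.0407) and in PAF49-GFP minus PAF49 (0.00883 and -0.0536). Against PAF49, PAF49deltaIDR-GFP was higher by 0.338 at 28S-Gm4618 and by 0.124 at 28S-Um4620. By base, the median range over the 4 libraries was 0.0142 at adenosine, 0.0277 at cytidine, 0.0266 at guanosine and 0.0429 at uridine sites, without allowance for their different levels. No graded order of PAF49-GFP and both deletions stood out in the scores as deposited. Where equal shares of the 6 orders give 18 sites, the order from PAF49-GFP up through PAF49delta1/2IDR-GFP to PAF49deltaIDR-GFP held at 21 and its reverse at 12. PAF49delta1/2IDR-GFP was highest at 26 sites with PAF49deltaIDR-GFP lowest and at 21 with PAF49-GFP lowest. PAF49delta1/2IDR-GFP was lowest at 21 sites with PAF49deltaIDR-GFP highest and at 7 with PAF49-GFP highest.

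PAF49 and PAF49delta1/2IDR-GFP lay together on one side of PAF49-GFP and PAF49deltaIDR-GFP at 50 of 108 sites, more than the 33 and 25 of the other pairings, and no group of the design unites these libraries. A difference in overall score level would tend to separate this pair, since PAF49 had the lowest and PAF49delta1/2IDR-GFP the highest median and mean score. The pair lay above the others at 26 sites and below at 24. These values argue against level as the source of the count above equal shares. After quantile normalisation the pairing held at 47 sites, 1 more than the 46 set beforehand as 36 of 108 plus 2 binomial SDs. That test adds little, because a level difference would not favour this pairing. Its margin is also 1 site, for the most common of 3 pairings. Of the 83 sites that fell into any pairing, equal shares give 27.7 with 2 binomial SDs of 8.59, and both spreads take sites as independent. Level stays open for the excess over the deletion pairing, which was 17 sites as deposited (2 SDs 17.9), 24 after quantile normalisation (2 SDs 15.9) and 4, from 46 against 42, with libraries shifted to the same median (2 SDs 18.7). The modified base stays open: the median contrast between the pairs lay at the 79.2, 64.2 and 50.5 percentile of matched random lists for adenosine, cytidine and guanosine sites and at 2.37 for uridine sites (-0.00990), the most extreme of 4, but the pair was higher at 6 and lower at 7 of the 13 uridine sites that showed the pairing. At the other bases 37 of 87 sites showed it, against 29 for equal shares with 2 binomial SDs of 8.79. Regional differences along the rRNA stay open too, since the contrast correlated between sites within 10 nt with r 0.210 (40 pairs, 91.1 percentile of random pairings), and no biological explanation was tested.

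The SD over sites of the difference from PAF49 was 0.0250 for PAF49delta1/2IDR-GFP and 0.0517 for PAF49deltaIDR-GFP, and from PAF49-GFP it was 0.0367 and 0.0400. These average 0.0384, beside 0.0383 for the mean of the full-length pair (0.0352) and the deletion pair (0.0414), a ratio of 1.001. For the pairing of PAF49 with PAF49delta1/2IDR-GFP the same ratio was 1.27, and for that of PAF49 with PAF49deltaIDR-GFP it was 0.801. With 1 library per group, these values do not separate an influence of the deletions from variation between libraries. PAF49deltaIDR-GFP lay above both full-length libraries by 0.1 or more at 3 sites, 28S-Cm2824 (0.129), 18S-Gm867 (0.144) and 28S-Gm4618 (0.135). The full-length libraries differed there by 0.00181, 0.0110 and 0.203. These sites were picked for their values, and 1 difference does not measure a site's spread. Over sites, the SD of the full-length difference was 0.0497 at mean scores from 0.5 to 0.9 and 0.0471 under 0.5. After quantile normalisation 28S-Cm2824 differed from PAF49-GFP by 0.0807.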
